A study of Homo sapiens with 6 samples.

How the data were processed

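Gene-level RNA-seq values were analysed for 6 libraries of CAL-62 cells, 2 each after 6 h with DMSO, 100 nM THZ531 or 400 nM THZ531. Total RNA was extracted with TRIzol and sequenced on Illumina instruments, per the labels' protocols. The submitters' processing notes name Bowtie2, DESeq2 and the hg19 genome, without versions; the counting tool, strand setting and RNA selection are not given in the sources used here. The deposited files hold 1 signal value per gene symbol, which the authors had already scaled between libraries, as the values themselves show.

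Each library's values were whole multiples of 1 step. Dividing by that step gave whole reads for 100% of values within a tolerance of 0.01 read, so the values are read numbers divided by a library factor of 1.22 and 1.18 in DMSO, 0.902 and 0.831 at 100 nM, and 0.868 and 0.814 at 400 nM. The ratios of these factors to median-of-ratios size factors recomputed from the recovered reads, divided by their geometric mean over the libraries, were 0.985 to 1.016. The recovered reads came to 37344224 to 43551280 per library. The files listed 15267 to 16018 genes, each with at least 1 read; a gene missing from a file was taken as 0. The floor of 3 reads corresponds to values of 2.46 to 3.69, and it covers counting error only. EEF1A1 took the largest share in every library, 1.03% to 1.92%, and the 10 highest genes 4.76% to 7.87%. Symbols listed more than once (21) were left out of tests; they held 0.136% to 0.177% of the values.

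2 features of the files limit single genes. Among read numbers up to 20, odd numbers made up 55.0% in DMSO replicate 2 and 24.9% to 28.0% in the other 5 libraries, so low read numbers were mostly even there. Whether mates of a pair were counted separately is not given in the sources used here, so the read totals, the floor of 3 reads and the chi-square between replicates may count fragments more than once. The 68 listed protein-coding genes of the major histocompatibility region had medians of 1 to 3.5 reads per library against 386 to 785 for 15159 others, so no change is read from single genes there, such as IER3 and NELFE, which stay in the list counts. No mitochondrially encoded mRNA was listed.

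The planned test, edgeR's quasi-likelihood test, assumed raw counts. Because the deposited values are scaled, the main test was limma with a mean-variance trend on log2(value + 1), and edgeR on the recovered reads became an alternative. Genes with a value of at least 10 in at least 2 libraries were tested (13742 of 17277 symbols). All 6 libraries entered 1 fit with a term per group, so that the groups share 1 estimate of spread, and p-values were adjusted by Benjamini-Hochberg at 0.05 over the genes of a comparison. A fold change is on the log2(value + 1) scale, which understates the change of low genes. The 3 comparisons were 100 nM against DMSO, 400 nM against DMSO and 400 nM against 100 nM.

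The comparisons, gene lists, rule for named genes and most alternatives were set before the data were examined. Named genes are CDK12, CDK13 and CCNK; for each dose the 10 largest called rises and 10 largest falls with a mean log2 CPM of at least 3 and libraries that do not overlap (5 and 5 between doses); up to 4 called members per list and dose with a mean log2 CPM of at least 1; BRCA1, BRCA2, FANCD2, FANCI, ATM, ATR and CHEK1; and the 5 genes with the largest opposite changes. Not every gene that the rule selects is described, and some are not reported here. The 23 lists, of which the mitochondrially encoded mRNAs had 0 measured members, were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured, two-sided, adjusted over the lists of a comparison. Other cell types were covered by leukocyte and endothelial markers.

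Gene symbols were matched to GENCODE v29 on GRCh38 for 13370 tested genes (97.3%), 12643 of the tested genes being protein coding. The files use hg19, so no coordinates are given and lengths serve only as gene properties.

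The fits were tested on simulated reads with the real means, library sizes and dispersions, with known changes planted. Changes were planted in a small share of the genes, all well above the filter, and the reads were scaled by their true library factors. The rates below therefore do not cover low genes, or comparisons in which most genes change and the scaling is uncertain. For 100 nM against DMSO, over 12959 genes, limma recovered 44 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 13 false calls among 12719 unchanged genes. For 400 nM against DMSO, over 12971 genes, 70.1%, 89.6% and 100% were recovered, with 19 false calls among 12731. For 400 nM against 100 nM, over 13236 genes, 82.1%, 86.6% and 100% were recovered, with 14 false calls among 12996.

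Alternatives were DESeq2 on recovered reads; recomputed median-of-ratios, total-count and upper quartile scaling; scaling to ribosomal protein mRNAs; no filter, or 1 CPM in 2 libraries; robust spread; a fit on the 4 libraries compared; a replicate block; a test against a minimum fold of 1.5; a 2-fold minimum; and leaving out each library. Chosen after the data were seen were edgeR on recovered reads, as such and with the reads of the 5 libraries with mostly even numbers halved, TMM scaling, and pseudocounts of 0.5 and 10. edgeR called 9872, 9619 and 7841 genes in the 3 comparisons. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.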

Results

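RNA was sequenced from CAL-62, a human line of anaplastic thyroid carcinoma, an undifferentiated and aggressive thyroid cancer. The cells had received vehicle (DMSO) or THZ531 for 6 h. THZ531 is a covalent inhibitor of CDK12 and CDK13, kinases that phosphorylate the C-terminal domain of RNA polymerase II during transcription elongation. There were 3 groups of 2 libraries each, namely DMSO, 100 nM THZ531 and 400 nM THZ531. The libraries held 43062794 and 41323819 gene-assigned reads in DMSO, 43551280 and 39026461 at 100 nM, and 41200316 and 37344224 at 400 nM. Levels are the deposited values, which are reads divided by a factor for each library, and are given as mean ± SD with n = 2 libraries per group. Replicates of each group differed by more than the sampling noise of independent reads, with a chi-square per degree of freedom of 6.12 in DMSO, 14.6 at 100 nM and 8.18 at 400 nM. The labels do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

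The first comparison concerned the mRNAs of the inhibitor's own targets. CDK12 mRNA was lower at both doses, at 8866 ± 75.3 in DMSO, 3354 ± 23.0 at 100 nM and 2569 ± 120.3 at 400 nM. CDK13 mRNA rose from 3178 ± 23.9 to 7586 ± 648 at 100 nM and was below the vehicle level at 400 nM, with 2253 ± 31.7. CCNK, which encodes cyclin K, the partner of both kinases, rose from 1212 ± 1.48 to 2060.1 ± 111 at 100 nM and stood at 1115 ± 124 at 400 nM. In limma the log2 fold changes of CDK12 were -1.40 ± 0.06 (SE) at 100 nM, adjusted p = 1.3e-07, and -1.79 ± 0.06 at 400 nM, adjusted p = 6.3e-08. Those of CDK13 were 1.25 ± 0.07, adjusted p = 4.6e-07, and -0.50 ± 0.07, adjusted p = 1.4e-04. CCNK changed by 0.76 ± 0.09 at 100 nM, adjusted p = 5.1e-05, and its value of -0.12 ± 0.09 at 400 nM did not pass, adjusted p = 0.241. With libraries scaled to the ribosomal protein mRNAs, the change of CDK13 at 100 nM was 0.26 and not called, and that of CCNK turned to -0.23. CCNK at 400 nM was called lower under total-count scaling, at -0.54, and under several other settings.

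**Figure D1:**
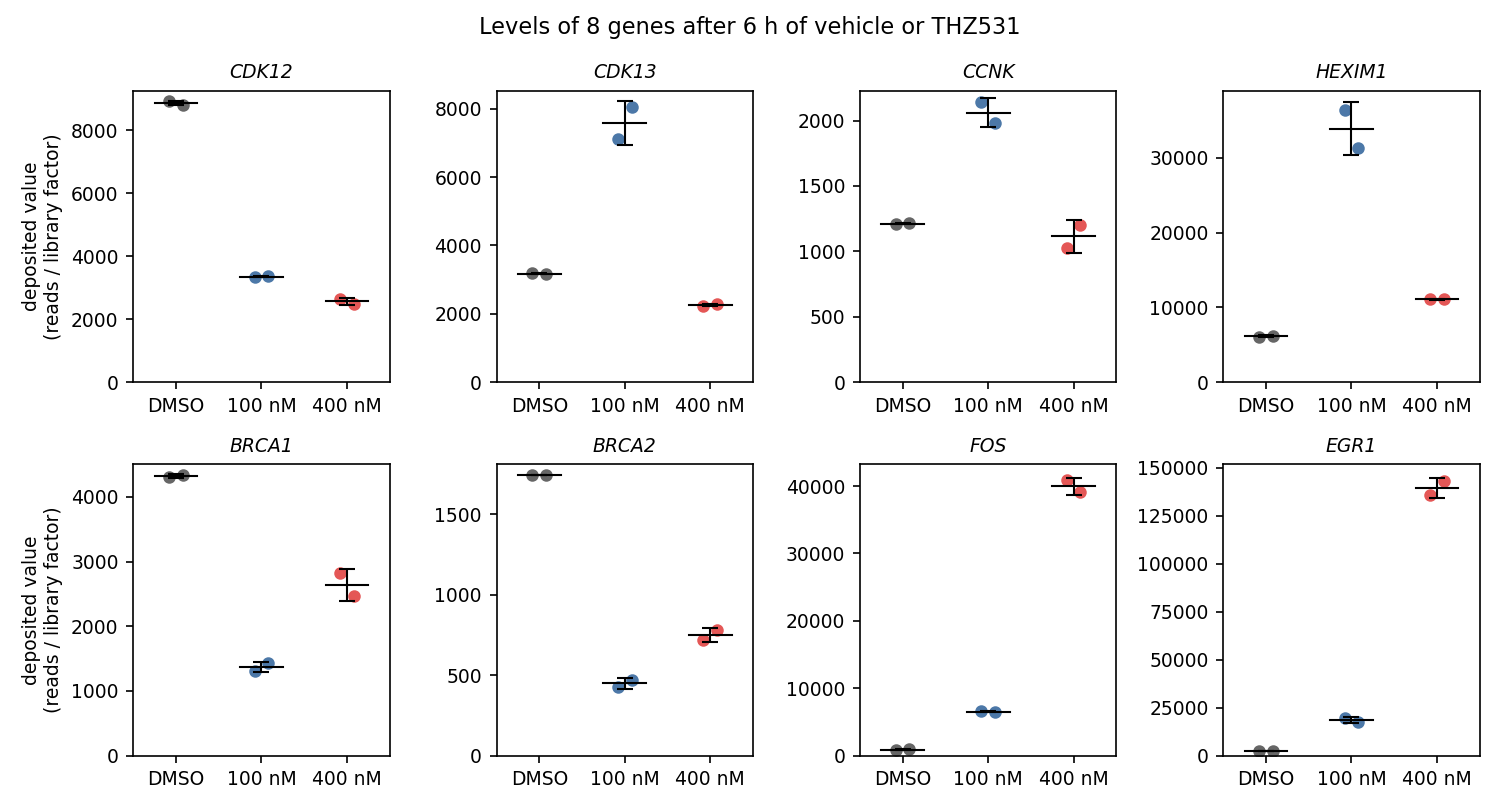
Deposited value (reads divided by the library factor, linear axis from 0) of 8 genes in each library of DMSO, 100 nM and 400 nM THZ531; points are libraries, the horizontal line is the group mean and the bar its SD (n = 2). CDK12 fell from 8866 to 2569 at 400 nM, while CDK13 and HEXIM1 were highest at 100 nM, with 7586 and 33894, and FOS and EGR1 highest at 400 nM, with 39986 and 139599.

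The comparison of 100 nM with vehicle asked which transcripts respond to the low dose. Among genes with a mean log2 CPM of at least 3, the largest rise was that of ARC, a growth-factor and activity-induced immediate-early gene, from 35.8 ± 1.96 to 4242 ± 805. RASD1, a Ras-like GTPase, rose from 27.4 ± 0.57 to 1260.4 ± 259, and SNAI1, a repressor of epithelial genes, from 168 ± 17.8 to 3579 ± 283. The other large rises were in ICAM5 (4.40 ± 0.09 on the log2 scale), MEX3B (4.29 ± 0.18), LAG3 (3.87 ± 0.13), the transcriptional co-regulator CITED2 (3.85 ± 0.09), ZNF296 (3.82 ± 0.13) and the small GTPase RHOB (3.75 ± 0.07). The deepest falls at this level of expression were in the diacylglycerol kinase DGKG, from 1268 ± 12.6 to 136 ± 10.8, and in TAB1, an adaptor of the kinase TAK1, from 2091 ± 12 to 252 ± 21.2. SLC38A9, an amino acid sensor of the lysosome, fell by 2.86 ± 0.13, followed by WBP1L (-2.82 ± 0.11), TRIM66 (-2.75 ± 0.11), the nuclease scaffold SLX4 (-2.74 ± 0.12), the cohesin loader subunit MAU2 (-2.72 ± 0.08), JPH1 (-2.67 ± 0.12), GTPBP2 (-2.60 ± 0.11) and MOB3A (-2.59 ± 0.23). Among these genes the highest adjusted p in limma was 8.5e-06, for MOB3A. DDT, at 4.22 ± 1.66, also ranked among the rises, but its DMSO libraries held 1080.3 and 7.60, and it can share reads with its near-identical neighbour DDTL. Without the lower DMSO library its change was 0.73, and most other settings ended its call.

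Genes of homologous recombination and of the Fanconi anaemia pathway, which repair DNA double-strand breaks and crosslinks, were mostly lower at 100 nM. Of 47 measured, 29 fell and 7 rose (camera, adjusted p = 4.2e-04; adjusted p = 0.40 with an estimated correlation). BRCA2 fell from 1744 ± 0.866 to 448 ± 33.6 and BRCA1 from 4322 ± 31.9 to 1371 ± 82.6, log2 fold changes of -1.96 ± 0.09 and -1.66 ± 0.08. RAD52 (-2.40 ± 0.14), MUS81 (-2.31 ± 0.09) and TOP3A (-2.01 ± 0.08) fell further. FANCI (-0.42 ± 0.05) fell, whereas FANCD2, at 0.13 ± 0.06, did not pass, adjusted p = 0.0723. Of 20 checkpoint kinases and mediators, which signal DNA damage, 13 fell and 5 rose (adjusted p = 0.0334; adjusted p = 0.40 with an estimated correlation). They included ATRIP (-2.05 ± 0.19), ETAA1 (-1.54 ± 0.12), ATR (-0.82 ± 0.06) and ATM (-0.49 ± 0.08). CHEK1 was called higher at 0.16 ± 0.06, adjusted p = 0.0442; that call ended under many settings, and CHEK1 turned to -0.28 under total-count scaling. KRAB zinc finger genes, which encode repressors with short-lived mRNAs, fell in 31 of 41 and rose in 2 (adjusted p = 1.4e-06; adjusted p = 0.40 with an estimated correlation). ZNF254 (-2.43 ± 0.17), ZNF41 (-2.39 ± 0.14) and ZNF202 (-2.36 ± 0.13) fell most, although members of this family can share reads. The medians of these 3 lists stayed below 0 under every scaling. Every other scaling moved the median of all genes down from its deposited 0.06, so none of them could have turned these lists.

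The lists that rose at 100 nM included the immediate-early genes, which respond within minutes to growth factors and stress: 26 of 32 rose and 3 fell (adjusted p = 1.8e-07; adjusted p = 0.40 with an estimated correlation). SGK1 rose from 733 ± 7.91 to 9656 ± 127, CTGF from 4113 ± 5.64 to 51166 ± 1222, and IER5 from 2517 ± 17.3 to 19396 ± 1463. Of 15 replication-dependent histone genes 14 rose (adjusted p = 5.1e-04; adjusted p = 0.40 with an estimated correlation), with HIST2H2BE at 3.95 ± 0.16 and HIST1H4H at 1.92 ± 0.17. These mRNAs mostly lack a poly(A) tail, near-identical copies can share reads, and the RNA selection is not given in the sources used here, so their values are uncertain. Cytosolic ribosomal protein genes rose in 67 of 69 and fell in none (adjusted p = 1.2e-15; adjusted p = 0.40 with an estimated correlation), and genes of oxidative phosphorylation in 50 of 53, with none lower (adjusted p = 1.9e-11; adjusted p = 0.402 with an estimated correlation). RPS9 (1.25 ± 0.08), RPLP0 (1.23 ± 0.08), NDUFA12 (1.28 ± 0.07) and the ATP synthase subunit ATP5B (1.10 ± 0.07) were among them, and ribosomal protein genes have many processed pseudogenes that can share reads. Mesenchymal and matrix genes rose in 22 of 28 and fell in 3 (adjusted p = 0.00250; adjusted p = 0.40 with an estimated correlation), as in the matrix protein THBS1 (2.76 ± 0.11). Genes of ATF4 and the unfolded protein response, which answer amino acid and endoplasmic reticulum stress, rose in 21 of 30 and fell in 7 (adjusted p = 0.0125; adjusted p = 0.40 with an estimated correlation), including DDIT4 (1.84 ± 0.15), ERN1 (1.65 ± 0.11), CRELD2 (1.65 ± 0.08) and CEBPB (1.58 ± 0.07). Heat shock genes rose in 11 of 19 and fell in 3 (adjusted p = 0.0334; adjusted p = 0.420 with an estimated correlation), with HSPB1 at 1.19 ± 0.07 and HSPA8 at 1.19 ± 0.06. The heat shock call ended under total-count scaling, adjusted p = 0.120, and without 100 nM replicate 1, adjusted p = 0.0578, in a range of 0.0183 to 0.420 over its alternatives with camera. With libraries scaled to the ribosomal protein mRNAs, which by construction leaves no test of that list itself, the medians of the oxidative phosphorylation, mesenchymal, ATF4 and heat shock lists turned below 0, and those of the immediate-early and histone lists stayed above 0, at 0.83 and 0.72.

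The other lists were not called at 100 nM. The elongation machinery had 21 of 37 members higher and 10 lower (adjusted p = 0.0677), among them HEXIM1, an inhibitor of the elongation kinase P-TEFb, from 6125 ± 133 to 33894 ± 3555, ELL2 (1.74 ± 0.13) and MEPCE, a capping enzyme of the 7SK RNA (-1.42 ± 0.08). Counts of higher and lower genes were 17 and 22 of 44 for G2/M and mitosis (adjusted p = 0.382), 21 and 18 of 46 for DNA replication (adjusted p = 0.838) and 13 and 5 of 24 for ERK pathway output (adjusted p = 0.0909). SGO1 (-2.25 ± 0.20), ASPM (-1.81 ± 0.07) and GINS1 (-2.22 ± 0.06) fell, while UBE2C (1.52 ± 0.05), PHLDA1 (1.56 ± 0.06) and MYC (1.56 ± 0.07) rose. Those counts were 17 and 8 of 31 for MYC targets (adjusted p = 0.158), 14 and 8 of 26 for p53 targets (adjusted p = 0.378), 9 and 14 of 29 for apoptosis regulators (adjusted p = 0.158), 16 and 10 of 27 for NF-kB targets (adjusted p = 0.429) and 16 and 3 of 23 for cholesterol synthesis (adjusted p = 0.0647). NOP56 (1.83 ± 0.06), the p53 targets GADD45A (2.03 ± 0.07) and BBC3 (1.92 ± 0.22), and PMAIP1 (1.73 ± 0.07) rose, and the apoptosis genes BIRC3 (-1.98 ± 0.12) and FADD (-1.95 ± 0.11) fell. Of 10 thyroid differentiation genes 2 rose and 5 fell (adjusted p = 0.838); the 2 were HHEX (2.41 ± 0.06) and PAX8 (0.95 ± 0.06), transcription factors of thyroid cells. Markers of other cell types were also read: 6 of 10 leukocyte markers were higher and none lower (adjusted p = 0.0849), and 2 of 7 endothelial markers were higher and 1 lower (adjusted p = 0.927). The 8 leukocyte markers called at either dose summed to values of 48.3 and 136 in the DMSO libraries and 773 and 358 at 100 nM. They were chosen as called higher, so this rise follows in part from the choice, and the uncalled CD8A and CD14 are not in the sum. Adjusted over the list alone, the counts at 100 nM were the same except for the MYC targets, with 9 lower. The median and mean differed in sign for DNA replication (0.10 and -0.11) and the endothelial markers (-0.27 and 0.57), and for the thyroid list fry and the median (-1.14) did. Under total counts and under the ribosomal protein reference the medians of the elongation, DNA replication, ERK, MYC, p53 and cholesterol lists turned below 0, and that of the NF-kB list did under the ribosomal protein reference. With total counts the higher and lower members were 4 and 9 for cholesterol and 7 and 28 for DNA replication, so the balance of these counts depends on the scaling. Some of these lists were called under other settings: the elongation machinery and ERK output without DMSO replicate 1 (adjusted p = 0.0266 and 0.0356) or DMSO replicate 2 (adjusted p = 0.0402 for each), cholesterol synthesis without 100 nM replicate 2 (adjusted p = 0.0183), and the leukocyte markers under total counts (adjusted p = 0.0103) and without DMSO replicate 2 (adjusted p = 0.0304).

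Of 13742 genes tested, 9820 (71.5%) differed between 100 nM and vehicle in limma, 5196 higher and 4624 lower, and 4152 of them by at least 2-fold, 1990 higher and 2162 lower. The libraries of both groups did not overlap for 9819 of the 9820, which largely follows from the call itself with 2 libraries per group. Direction depends on the scaling: the median log2 fold change of all genes was 0.06 as deposited, -0.37 with total counts and -0.92 with the ribosomal protein mRNAs as reference. The calls split into 3025 higher and 6977 lower under total counts and 1093 higher and 9741 lower under the ribosomal protein reference.

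The comparison of 400 nM with vehicle asked the same of the higher dose. Among genes with a mean log2 CPM of at least 3, the largest rises included several immediate-early genes. EGR1, a zinc finger transcription factor, went from 2475 ± 7.01 in DMSO to 139599 ± 5269.9, FOS, a subunit of AP-1, from 912 ± 42.5 to 39986 ± 1267, and ARC from 35.8 ± 1.96 to 22567 ± 669. RASD1 (5.34 ± 0.15 on the log2 scale), ICAM5 (5.28 ± 0.09), IER2 (4.44 ± 0.07), the mRNA decay factor ZFP36 (4.15 ± 0.09), GLIS2 (3.58 ± 0.15) and SGK1 (3.43 ± 0.05) followed. The deepest fall among them was in CMTR2, a cap methyltransferase, from 2186 ± 34.7 to 153 ± 5.62, then in the splicing factor RBM5, from 2023 ± 12.4 to 179 ± 56.6. ZBED5 (-3.25 ± 0.16), ZNF133 (-3.22 ± 0.14), PRDM4 (-3.14 ± 0.16), the helicase DDX20 (-3.07 ± 0.12), the mitochondrial ubiquitin ligase MUL1 (-3.03 ± 0.13), the nucleotide receptor P2RY2 (-2.92 ± 0.12) and PIP4P1 (-2.81 ± 0.17) also fell. Among these genes the highest adjusted p was 9.8e-07, for PIP4P1. DDT, at 4.55 ± 1.66, rests on the same DMSO library as at 100 nM, and was 1.06 without it.

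Repair genes were again mostly lower at 400 nM. Of the 47 homologous recombination and Fanconi genes 26 fell and 5 rose (adjusted p = 9.1e-04; adjusted p = 0.381 with an estimated correlation), with RAD52 at -2.73 ± 0.14, SLX4 at -2.20 ± 0.12 and PALB2, which links BRCA1 to BRCA2, at -2.01 ± 0.12. BRCA2 was 750.3 ± 44.5, a log2 fold change of -1.22 ± 0.09, and BRCA1 2642 ± 246, a change of -0.71 ± 0.08. FANCD2 (0.22 ± 0.06) and FANCI (0.22 ± 0.05) were called higher, calls that ended under TMM scaling and became -0.19 and -0.19 under total counts. Checkpoint genes fell in 15 of 20 and rose in 3 (adjusted p = 0.00782; adjusted p = 0.308 with an estimated correlation), with ETAA1 at -2.63 ± 0.12, CLSPN at -1.02 ± 0.11, ATR at -0.43 ± 0.06 and CHEK1 at -0.33 ± 0.06. ATM was 1993 ± 119 against 1989.9 ± 3.94 in DMSO and was not called, adjusted p = 0.992. Genes of G2/M and mitosis fell in 30 of 44 and rose in 7 (adjusted p = 1.4e-04; adjusted p = 0.308 with an estimated correlation). The spindle checkpoint kinase TTK fell from 2643 ± 64.8 to 518 ± 17.0, and CDCA8 (-2.14 ± 0.08), SGO1 (-2.06 ± 0.20) and the mitotic kinase AURKA (-1.53 ± 0.05) fell with it. Apoptosis regulators fell in 19 of 29 and rose in 7 (adjusted p = 0.0323; adjusted p = 0.308 with an estimated correlation). Among the members that fell were BAK1 (-2.39 ± 0.10) and FADD (-2.10 ± 0.11), which promote cell death, and the inhibitor of apoptosis BIRC3 (-1.93 ± 0.12). That call ended under total-count scaling, adjusted p = 0.0719, and without 400 nM replicate 1, adjusted p = 0.0606, in a range of 0.0160 to 0.308 over its alternatives with camera. KRAB zinc finger genes fell in 35 of 41 and none rose (adjusted p = 3.9e-08; adjusted p = 0.308 with an estimated correlation), with ZNF184 at -3.14 ± 0.18, ZNF202 at -2.78 ± 0.13 and ZNF248 at -2.57 ± 0.16. The medians of these 5 lists stayed below 0 under every scaling. Only upper quartile factors moved the median of all genes up, from -0.02 to 0.07, so the scalings hardly put these lists to a test.

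Immediate-early genes rose in 23 of 32 and fell in 4 at 400 nM (adjusted p = 7.5e-06; adjusted p = 0.308 with an estimated correlation). Ribosomal protein genes rose in 68 of 69 (adjusted p = 4.3e-20; adjusted p = 0.381 with an estimated correlation) and oxidative phosphorylation genes in 51 of 53 (adjusted p = 6.3e-16; adjusted p = 0.381 with an estimated correlation), with none lower in either list. RPS9 was 83026 ± 3421 against 30627 ± 413 in DMSO, RPLP0 changed by 1.40 ± 0.08, NDUFA4 by 1.17 ± 0.06, COX4I1 by 1.17 ± 0.07 and ATP5B by 1.16 ± 0.07. Histone genes rose in 13 of 15 (adjusted p = 8.9e-04; adjusted p = 0.381 with an estimated correlation), with HIST2H2BE at 2.68 ± 0.16 and HIST1H4H at 2.45 ± 0.17. Mesenchymal genes rose in 21 of 28 and fell in 5 (adjusted p = 0.00268; adjusted p = 0.381 with an estimated correlation), with SNAI1 at 3.05 ± 0.11, THBS1 at 1.67 ± 0.11 and the actin-binding protein TAGLN at 1.42 ± 0.08. The medians of the oxidative phosphorylation and mesenchymal lists turned below 0 with the ribosomal protein mRNAs as reference, and those of the immediate-early and histone lists were then 0.51 and 0.30. Leukocyte markers were higher in 7 of 10, CD74 among them at 214 ± 17.4 against 42.7 ± 29.2, without passing as a list (adjusted p = 0.0703), although the list was called under total counts (adjusted p = 0.00599) and without DMSO replicate 2 (adjusted p = 0.0155). The 8 markers called at either dose summed to 434 and 558 at 400 nM, beside the DMSO values above, a rise that again follows in part from their choice.

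No other list was called at 400 nM. Higher and lower members numbered 11 and 18 of 37 for the elongation machinery (adjusted p = 0.244), 22 and 18 of 46 for DNA replication (adjusted p = 0.575), 8 and 10 of 24 for ERK output (adjusted p = 0.992), 16 and 12 of 31 for MYC targets (adjusted p = 0.487) and 9 and 9 of 26 for p53 targets (adjusted p = 0.934). Among them MEPCE (-2.54 ± 0.08), the elongation factor LEO1 (-1.43 ± 0.15), CDK8 (-1.25 ± 0.09), POLD3 (-1.61 ± 0.09) and the ribosome assembly factor RRS1 (-2.35 ± 0.08) fell, while MYC (1.85 ± 0.07) and GADD45A (2.0 ± 0.07) rose. The numbers were 17 and 9 of 30 for ATF4 and the unfolded protein response (adjusted p = 0.165), 9 and 6 of 19 for heat shock (adjusted p = 0.473), 10 and 16 of 27 for NF-kB targets (adjusted p = 0.697) and 11 and 7 of 23 for cholesterol synthesis (adjusted p = 0.487). TRIB3 (-2.32 ± 0.10), XBP1 (-1.71 ± 0.08), HSF2 (-1.56 ± 0.15), MVK (-1.68 ± 0.20) and SQLE (-1.25 ± 0.06) fell, and HSP90AB1 (1.27 ± 0.07) rose. Of the 10 thyroid genes 2 rose and 4 fell (adjusted p = 0.487), with HHEX at 1.87 ± 0.06 and PAX8 at -0.51 ± 0.06, and of 7 endothelial markers 1 rose and 1 fell (adjusted p = 0.575). Adjusted over the list alone, the counts were the same except for 31 lower G2/M genes, 9 higher leukocyte markers and no lower endothelial marker. The median and mean differed in sign for DNA replication (0.12 and -0.06), ERK output (-0.12 and 0.28), MYC targets (0.22 and -0.04), p53 targets (0.04 and -0.02), ATF4 (0.25 and -0.01) and cholesterol (0.25 and -0.02), and fry ran against the median of the NF-kB list (-0.42). Under total counts and under the ribosomal protein reference the medians of the ATF4, heat shock, DNA replication, MYC, p53 and cholesterol lists turned below 0, and that of the endothelial markers did under the ribosomal protein reference. With total counts the higher and lower members were 10 and 16 for ATF4 and 5 and 11 for heat shock.

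At 400 nM 9485 genes differed from vehicle, 4715 higher and 4770 lower, and 3730 by at least 2-fold, 1627 higher and 2103 lower. The libraries did not overlap for any of the 9485, which again largely follows from the call itself. The median log2 fold change of all genes was -0.02 as deposited, -0.17 with TMM, -0.43 with total counts and -1.18 with the ribosomal protein reference. The calls split into 2782 higher and 7022 lower under total counts and 586 higher and 10836 lower under the ribosomal protein reference.

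**Figure D2:**
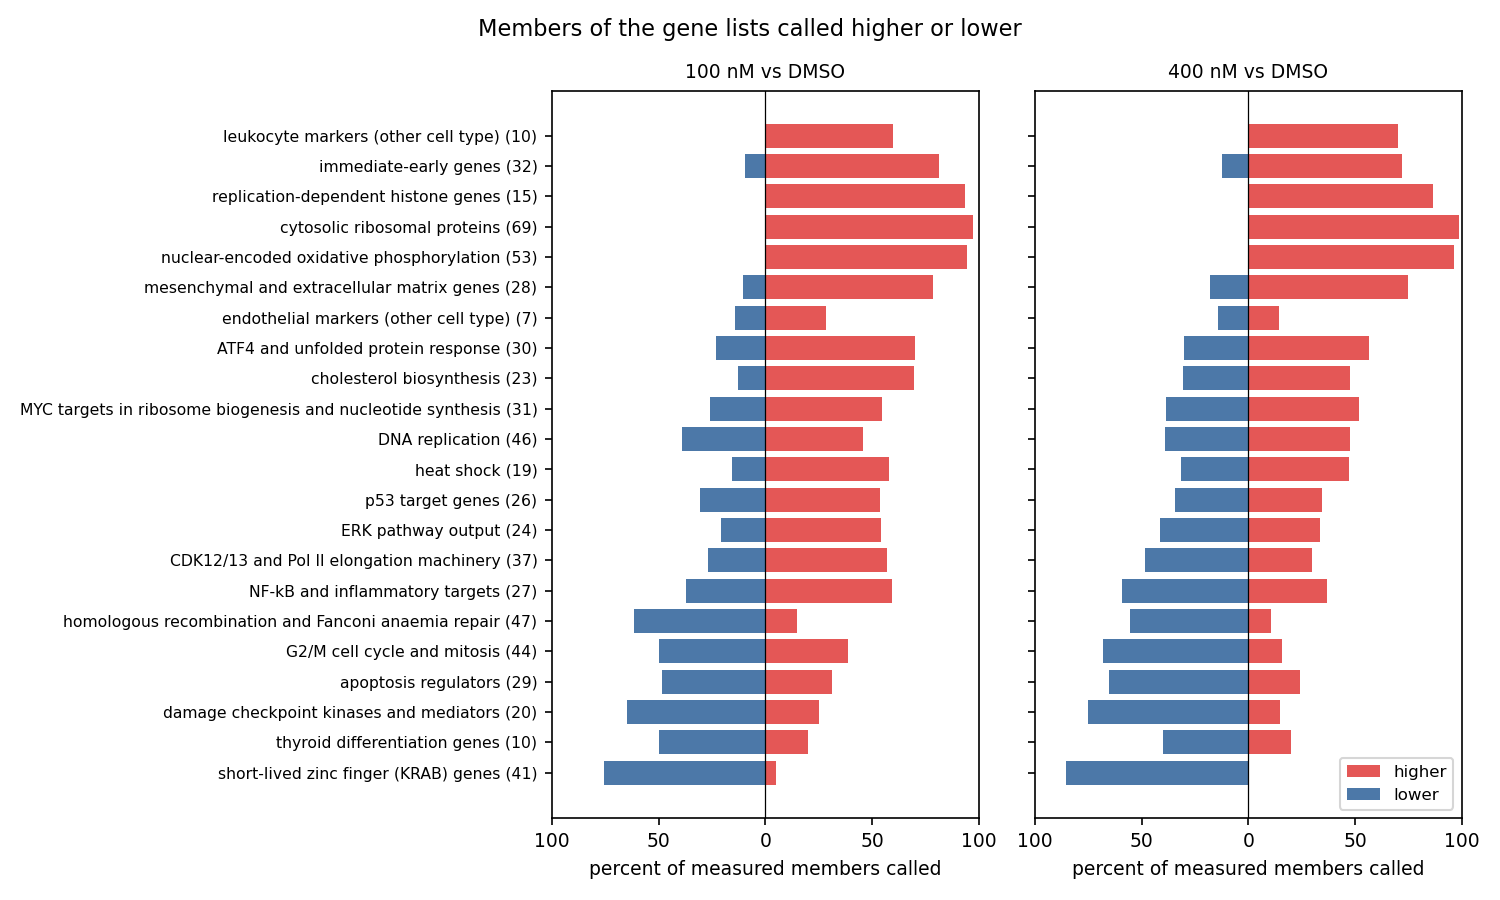
Percent of the measured members of each gene list called higher (red, to the right) or lower (blue, to the left) than DMSO at 100 nM (left panel) and 400 nM (right panel), with the number measured in parentheses. Ribosomal protein genes were higher in 67 and 68 of 69 and KRAB zinc finger genes lower in 31 and 35 of 41.

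The direct comparison of both doses tested which changes depend on dose. Of the genes with large rises, EGR1 was 7.57 times as high at 400 nM as at 100 nM, FOS 6.11 times and ARC 5.32 times. METTL23 (2.16 ± 0.13) and LMLN (2.08 ± 0.12) were also higher. With the same minimum of expression, the deepest falls from 100 to 400 nM were in TFAP2C, a transcription factor, from 965 ± 23.0 to 112 ± 34.4, the phosphodiesterase PDE4D, from 1281 ± 106 to 161 ± 48.6, FAM117B (-2.92 ± 0.11), PDE7A (-2.91 ± 0.11) and TMEM131L (-2.80 ± 0.11). HEXIM1 (-1.61 ± 0.07), CDK13 (-1.75 ± 0.07), CDK12 (-0.39 ± 0.06) and CCNK (-0.89 ± 0.09) were lower at 400 nM than at 100 nM. BRCA1 (0.94 ± 0.08), BRCA2 (0.74 ± 0.09), FANCI (0.64 ± 0.05), ATM (0.49 ± 0.08) and ATR (0.39 ± 0.06) were higher at 400 nM than at 100 nM. Among the genes of this paragraph the highest adjusted p was 7.1e-04, for ATM.

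As a group the elongation machinery was lower at 400 nM than at 100 nM, with 22 of 37 members lower and 6 higher (adjusted p = 6.6e-04; adjusted p = 0.433 with an estimated correlation; 22 and 7 adjusted over the list alone). Genes of G2/M and mitosis were lower in 27 of 44 and higher in 6 (adjusted p = 6.6e-04; adjusted p = 0.740 with an estimated correlation), the same counts adjusted over the list alone. Ribosomal protein genes were higher in 30 of 69 and lower in none (adjusted p = 6.6e-04; adjusted p = 0.894 with an estimated correlation; 22 adjusted over the list alone). Oxidative phosphorylation genes were higher in 22 of 53 and lower in 2 (adjusted p = 0.00214; adjusted p = 0.894 with an estimated correlation; 21 and 1 adjusted over the list alone), and their median turned below 0 with the ribosomal protein reference. The number higher depends on the scaling, at 13 with TMM and 61 with upper quartile factors for the ribosomal protein genes and 15 and 46 for oxidative phosphorylation. Without 400 nM replicate 1 the oxidative phosphorylation call ended, adjusted p = 0.0572, in a range of 7.6e-05 to 0.894 over its alternatives with camera. For homologous recombination 17 of 47 were higher and 14 lower (adjusted p = 0.583), and for immediate-early genes 13 of 32 were higher and 14 lower (adjusted p = 0.972), with a median of -0.16 and a mean of 0.21. Their medians turned below 0 with the ribosomal protein reference and above 0 with upper quartile factors, respectively. No other list was called, and the lowest adjusted p among the rest was 0.156, for ATF4 and the unfolded protein response. In all, 8067 genes differed between the doses, 4178 higher and 3889 lower at 400 nM, and 2262 by at least 2-fold, 700 higher and 1562 lower. The calls split into 5576 higher and 3141 lower with upper quartile factors and 2261 higher and 4443 lower with the ribosomal protein reference.

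Most genes called at both doses moved the same way. Of 13742 genes, 3475 were higher at both and 3103 lower at both, where independent lists would share 1783 and 1605. A further 1089 were called in opposite directions, 820 higher at 100 nM and lower at 400 nM and 269 the reverse, where independent lists would give 1804 and 1587. Examples were TFAP2C (0.96 ± 0.19 and -2.18 ± 0.19), SHISA2 (1.40 ± 0.35 and -2.86 ± 0.35) and GNRH2 (-1.80 ± 0.44 and 2.60 ± 0.44). The call of SHISA2 at 100 nM ended without DMSO replicate 1, adjusted p = 0.0650, and with the ribosomal protein reference, adjusted p = 0.261. GDF9 (2.02 ± 0.57 and -1.45 ± 0.57) lay near the floor of 3 reads at 400 nM; its call there ended under many settings, and its call at 100 nM without DMSO replicate 1, adjusted p = 0.0996. The antisense gene SLC2A1-AS1, for which no strand is known, held 10.6 and 8.44 in DMSO, 0 and 2.41 at 100 nM, and 34.6 and 60.2 at 400 nM. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.761 and Spearman's rho 0.706; r averaged 0.50 in 20 simulations of unchanged groups against the same controls. The covariance was 1.18 against 0.0728 simulated, a difference of 1.10, and no gene was called at both doses in the simulations. With every gene unchanged there, the adjustment sets a stricter limit than in the data. That absence of calls therefore does not bound the calls that shared controls may add. Part of the excess may come from the shared controls, which at 2 libraries are too few to split. The number called in opposite directions was 687 without DMSO replicate 1, 699 without DMSO replicate 2 and 378 with the ribosomal protein reference, and 50 genes passed a test against a 1.5-fold minimum in opposite directions. The split by direction moved as well, to 591 higher at 100 nM and lower at 400 nM and 550 the reverse with upper quartile factors, 368 and 10 with the ribosomal protein reference, 572 and 115 without DMSO replicate 1 and 579 and 120 without DMSO replicate 2.

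**Figure D3:**
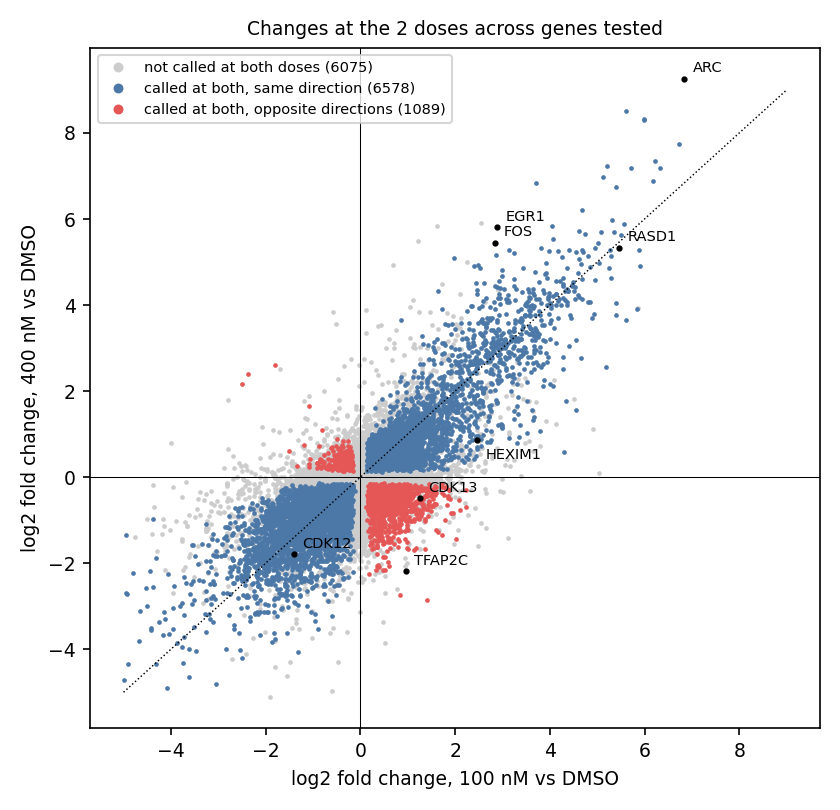
Log2 fold change at 400 nM against that at 100 nM, each against DMSO, for the 13742 genes tested; each point is a gene, blue points were called at both doses in the same direction (6578), red points in opposite directions (1089), and the dotted line marks equal change. ARC, EGR1 and FOS lie above the line and HEXIM1, CDK13 and TFAP2C below it.

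Because CDK12 and CDK13 act on elongating polymerase, changes were set against gene length. Lengths came from GRCh38 gene models, matched for 13370 genes (97.3%). Genes under 3 kb (507) had median log2 fold changes of 0.84 at 100 nM and 0.80 at 400 nM. Those of 3 to 10 kb (1933) had 0.36 and 0.39, and those of 30 to 100 kb (4475) had -0.13 and -0.17. Genes of 100 to 300 kb (2205) had 0.09 at 100 nM and -0.15 at 400 nM, and genes over 300 kb (592) had 0.40 and 0.24. All of these medians would lie lower under total-count scaling and the ribosomal protein reference, by about the shifts of the median of all genes given above. Across genes, Spearman's rho of fold change with genomic length was -0.0916 at 100 nM and -0.134 at 400 nM. Taken alone, the libraries gave -0.113 and -0.0673 at 100 nM and -0.138 and -0.125 at 400 nM. In the low, middle and high tertile of expression rho was -0.164, 0.0376 and -0.143 at 100 nM. At 400 nM it was -0.140, 0.0144 and -0.288 in these tertiles. With spliced length rho was -0.138 and -0.219, and with exon number -0.0594 and -0.0311.

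**Figure D4:**
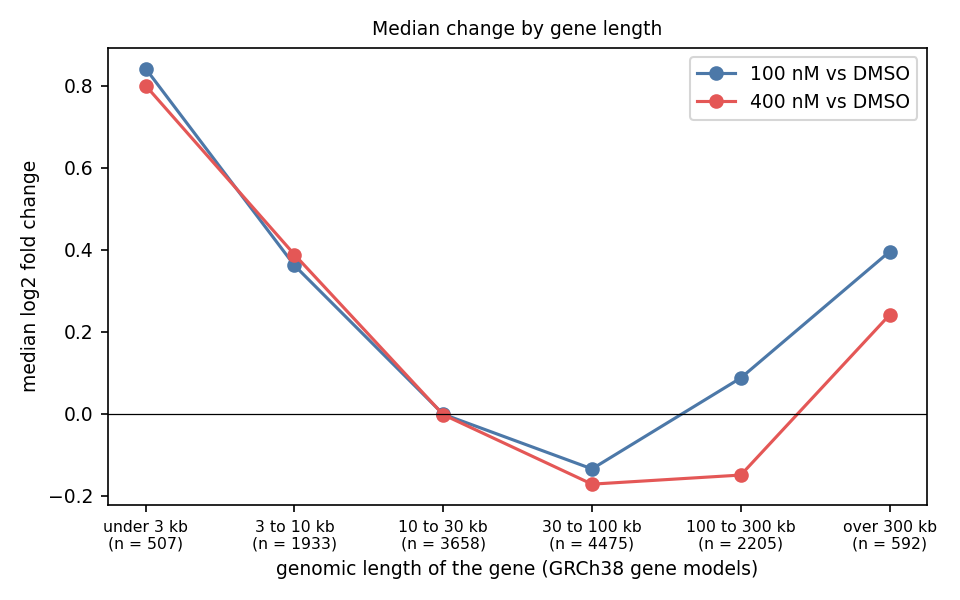
Median log2 fold change against DMSO of genes grouped by genomic length (kb, GRCh38 gene models; number of genes under each group) at 100 nM (blue) and 400 nM (red). The line is highest for genes under 3 kb, at 0.84 and 0.80, and lowest for genes of 30 to 100 kb, at -0.13 and -0.17, values that shift together with the scaling of the libraries.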

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

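Among the settings below, edgeR on recovered reads, its version with halved reads, TMM scaling and pseudocounts of 0.5 and 10, and every setting for the genes called in opposite directions, were chosen after the data were seen. Over the settings other than a minimum fold and the left-out libraries, 9246 to 10834 genes were called at 100 nM, 8956 to 11422 at 400 nM and 6704 to 8717 between the doses, all within 1.5 times the counts reported. These totals do not show direction. With the ribosomal protein reference, 5717 of 8073 calls shared with those reported kept their direction at 100 nM and 5356 of 8250 at 400 nM. Under total counts 7649 of 7996 and 7552 of 7766 did. Leaving out 1 library, where the lone library left in a group is assumed to vary like the other groups, gave 8352 to 9993, 8083 to 9868 and 7192 to 8086. By construction fewer passed a test against a 1.5-fold minimum (4503, 4132 and 2281) or a 2-fold minimum (4152, 3730 and 2262). Genes called in the same direction at both doses then numbered 2268 and 2126, and in opposite directions 50 and 19; without 1 library they numbered 5359 to 6682 and 687 to 1270. With the ribosomal protein reference 378 were opposite. The cause of these last differences was not tested.

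Of 24 list calls none held with an estimated correlation (0), and fry, which does not compare a list with other genes, called 52; without 1 library 22 to 28 were called. In the length relation at 400 nM, rho was -0.219 with spliced length, -0.0311 with exon number, 0.0144 and -0.288 in the middle and high expression tertiles and -0.124 with no filter; the cause was not tested.

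Of named genes, with the ribosomal protein reference these turned below 0 at 100 nM: CCNK (-0.23), TFAP2C (-0.0349), CHEK1 (-0.84), AURKA (-0.50) and PAX8 (-0.0444). At 400 nM HEXIM1 (-0.32), FANCD2 (-0.95), FANCI (-0.96), PMAIP1 (-0.38), PHLDA1 (-0.29), COX4I1 (-0.00902), ATP5B (-0.00971) and NDUFA4 (-0.00111) did. CCNK, TFAP2C and PAX8 at 100 nM and COX4I1, ATP5B and NDUFA4 at 400 nM were then not called. Under total counts CHEK1 at 100 nM (-0.28) and FANCD2 (-0.19) and FANCI (-0.19) at 400 nM turned. The shift of all genes by the reference accounts for the direction of these.

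The 211 gene results were recomputed 4851 times in all. Of these, 4698 counted as unchanged, 130 kept the direction but lost the call, 7 kept it and gained a call, and 16 called results turned. By the rule used, a result not called as reported counted as unchanged if its direction turned, whether or not it was then called. Of 726 list results 659 counted as unchanged, 36 gained a call and 31 lost one, 24 of the lost calls under the estimated correlation. By the same rule, new fry calls against camera's direction counted as unchanged. Such calls were those of the thyroid list at the lower dose and of the NF-kB and p53 lists at the higher dose. Little shared effect of the replicate numbers was seen, since deviations of same-numbered libraries correlated at -0.05, 0.11 and -0.04. Whether same-numbered libraries were handled together is not given in the sources used here. A replicate block gave 9900, 9560 and 8212 calls. Scaling to mitochondrially encoded mRNAs was not run, since none is listed. With 37344224 to 43551280 reads, depth limits mainly genes near the floor, such as GDF9.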

Other observations

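The tests of a second leukocyte list and of sets matched on spliced length were set before their results were seen, and the tests of the NF-kB list and of single genes were planned; the other tests of an explanation were chosen after. The NF-kB list was not called by camera at either dose (adjusted p = 0.429 at 100 nM and 0.697 at 400 nM), and its members went both ways. Of 27 measured, 16 were higher and 10 lower at 100 nM, and 10 higher and 16 lower at 400 nM, so the genes named next belong to the smaller side at each dose. At 400 nM the chemokine genes CXCL3 (779 ± 27.5 in DMSO and 3897 ± 84.7), CXCL8 (6633 ± 65.9 and 22699.5 ± 935) and CXCL2 (2482 ± 70.4 and 7117 ± 307) were higher. At 100 nM the adhesion molecule ICAM1 (-2.06 ± 0.12 on the log2 scale), the inhibitor NFKBIE (-1.70 ± 0.15) and the transcription factor IRF1 (-1.66 ± 0.10) were lower. Among p53 targets, GADD45A rose at both doses, to 6091 ± 297 and 5949.6 ± 475 from 1486 ± 7.75, while the repair gene XPC (-1.43 ± 0.10), the nuclease AEN (-1.48 ± 0.07) and SESN2 (-1.41 ± 0.10) fell at 400 nM. PPM1D, a phosphatase of the p53 pathway, was 749 ± 6.99 in DMSO, 2672 ± 283 at 100 nM and 742 ± 71.1 at 400 nM. INSIG1, a sterol sensor, fell at 400 nM (-1.31 ± 0.07), as did DUSP4 (-2.39 ± 0.22) and SPRY1 (-1.75 ± 0.20), feedback inhibitors of ERK signalling.

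Leukocyte transcripts appeared in an epithelial tumour line. PTPRC read 0 and 16.9 in DMSO, 142 and 54.2 at 100 nM, and 63.4 and 112 at 400 nM; LYZ read 0, 16.0, 104, 42.1, 53 and 79.9, S100A9 0, 16.0, 167, 57.8, 57.6 and 103, and CD74 22.1, 63.3, 328, 176, 202 and 226 in that order. The 8 called markers differed between the 100 nM replicates by a median ratio of 2.51, where random gene sets of the same level gave 0.693 to 1.6 (central 95% of 10000). Those sets hold unrelated genes, while the markers move together between replicates (estimated inter-gene correlation 0.480). Genes induced together could differ in this way too, so the ratio does not decide for or against induction by THZ531. A second list held 20 leukocyte genes, of which 13 were tested and 8 lay under a value of 30 in DMSO replicate 1. Those 8 had a median ratio of 1.98 against a 95th percentile of 1.43. RNA from another leukocyte source may give this, and so may genes induced together. The random sets here also hold unrelated genes, so this ratio does not decide either. Whether RNA from another source entered, and how much of the rise comes from the treatment, stays open. Those 8 genes of the second list summed to 54.8 and 122 in DMSO and 674, 311, 272 and 481 in the treated libraries.

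The 1089 genes called in opposite directions at both doses were examined for 3 explanations. A single deviating library is argued against as the whole cause, since at least 63.0% of them kept both calls without any 1 library, the lowest share being without DMSO replicate 1. Whether they come from the scaling or from the cells cannot be told apart: 34.8% kept both calls under total counts, against 75.3% under TMM, 79.0% under upper quartile and 94.1% under recomputed median-of-ratios factors; with the ribosomal protein reference 6.52% did. A shift of all genes alike ends the calls of small changes by construction, and 940 genes, 688 higher at 100 nM and lower at 400 nM and 252 the reverse, were opposite under total counts. The genes higher at 100 nM and lower at 400 nM were long, with a median of 53.1 kb over 809 genes. Random sets of genes higher at 100 nM matched on expression, but not on the size of the rise, gave 27.8 to 36.6 kb. Between the doses, rho of fold change with genomic length was -0.0408 over all genes. It was 0.0400, -0.0211 and -0.142 in the low, middle and high expression tertiles. A loss of long transcripts at the higher dose is therefore a candidate explanation that these values do not settle. A response of these cells to dose stays open too.

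Ribosomal protein and oxidative phosphorylation mRNAs rose together, with a median log2 fold change of 1.09 over 115 genes at 400 nM and 0.93 at 100 nM. Sets of other genes matched on spliced length and expression reached 0.78 to 0.94 at 400 nM and 0.68 to 0.81 at 100 nM, below the lists. Genes of those sets were drawn independently, while members of the 2 lists move together (estimated inter-gene correlations 0.635 and 0.619). Such ranges are too narrow for genes that move together, so they do not decide whether short spliced length is the whole cause. The match was close on spliced length, with medians of 1.747 kb for the lists and 1.697 kb for the other genes, and incomplete on expression, with a median log2 CPM of 8.70 against 8.35, so a part of the difference owing to expression stays open. Those sets were themselves well above the median of all genes. Since they were matched on both spliced length and expression, length, expression or both may account for part of the rise. A rise of these mRNAs and a fall of most others at constant ribosomal protein mRNA cannot be told apart, since no spike-in or cell number is used here; with these mRNAs as reference the median of all genes was -1.18 at 400 nM.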
